A study of Mus musculus with 4 samples.

How the data were processed

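Genomic DNA of 1 group of cells was measured in 4 technical replicates. The cells were E14 (ES-E14TG2a) mouse embryonic stem cells, a clone carrying lentiviral dCas9-VP64 and MS2-p65-HSF1 activator constructs, grown in serum with leukaemia inhibitory factor. Per the labels, each replicate used 80 ng of sonicated DNA in the biomodal workflow, which reads the genetic bases together with 5-methylcytosine (5mC) and 5-hydroxymethylcytosine (5hmC). The replicates share 1 DNA source as far as the labels tell, so every p-value over replicates measures technical spread alone.

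The deposited files hold counts per CpG cytosine and strand, without a header. Per the submitters' processing notes, cutadapt 4.1, BWA 0.7.17, SAMtools 1.15, Picard and Bismark were used with the GRCm38 genome build; the role and settings of each are not given in the sources used here. The files name no columns. The columns were read as 5mC count, 5hmC count, unmodified count and depth from their values: mitochondrial cytosines fell almost wholly in 1 column, taken as unmodified, and of the other columns the more frequent was taken as 5mC. The depth exceeds the sum of the 3 call classes by 5.64% to 5.70% of reads per replicate, and these reads entered no level. All 4 files list the same 26371566 cytosines. The 114 contigs beyond the primary chromosomes held at most 0.0816% of the calls and were left out.

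The replicates held 543003173, 566803554, 521879873 and 709778597 calls, with medians of 22, 23, 21 and 28 calls per cytosine. Between 5.55% and 5.60% of the listed cytosines had no call in a given replicate. A level is the summed calls of a modification divided by all calls in the 3 classes, as a percent, with the mean and SD over replicates. Mitochondrial cytosines served as a measure of false calls. Their calls numbered 60157 to 60325 in every replicate despite unequal depth, so that a limit on depth there appears to apply. Intervals and floors cover counting error alone; a share of 0 is given with the limit that 3 counts would set.

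Gene positions came from a RefSeq table of the same build, matched by symbol and synonym. That table gives the start and end of genes, and neither strand nor exons. The planned promoter, exon, UTR and intron classes and the coding against template strand comparison were therefore not run. In place of the promoter, the window within 500 bp of the gene start or end that held more listed CpGs was taken and is called the CpG-denser end; 855 coding genes had equal numbers at both, and the lower coordinate was used. For CpG-poor genes this end need not be the promoter. For single genes and gene lists, bodies ran from 1000 bp inside 1 end to 1000 bp inside the other. For the comparison of regions, bodies were the sequence of coding genes outside the 500-bp windows of gene ends. The alternative with ends of 1000 bp widened the CpG-denser end alone. These definitions, the removal of LOC symbols from named genes, the comparisons of the strands of single CpGs and of the plus and minus strands, the alternatives that leave out CpGs lost in the cell line or adjust gene calls over 1 list alone, and the tests of explanations were chosen after the files had been seen. The gene lists, the tests of windows, regions, genes and lists, and the other alternatives were fixed before.

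Replicates were compared by a chi-square test of homogeneity in 10-kb windows with at least 100 calls per replicate and expected counts of at least 5, with Benjamini-Hochberg (BH) adjustment at 0.05. Genes were tested by a quasi-binomial z test of pooled counts against the level over all gene bodies, with the variance multiplied by the dispersion between replicates; a call needed BH 0.05 and the same side in all 4 replicates. Bodies needed 20 CpGs and 200 calls, and gene ends 5 CpGs and 50 calls. Differences between regions were tested by two-sided exact sign flips over the 4 replicates, whose smallest p is 1 in 8, and by a two-sided permutation with 100000 sign flips over the 19 autosomes, which describes how uniform a difference is over the genome. Each of 14 gene lists was compared with 10000 random lists of coding genes matched on decile of CpG number, and the 42 permutation p-values were BH adjusted. Random genes were drawn from the whole genome, and list members were not removed from the draw. Where list members lie close together, as Hox, olfactory receptor and some imprinted genes do, they are not independent and the p-values may be too small. The strands of a CpG were compared by Fisher's exact test with at least 20 pooled calls per strand. Levels of 5hmC by total modification were read in 1 pair of replicates within 1-kb windows binned in the other pair, both ways. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9 were used.

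The named genes were set by a rule. Among tested coding genes without a predicted symbol, these were the 8 highest and 8 lowest called gene bodies in 5hmC and the 6 highest gene ends in 5hmC with at least 10 CpGs. From each list the 2 highest and 2 lowest members in gene-body 5hmC were added, or in gene-end 5mC for germline and imprinted genes; any measured imprinted gene could be named. Members of near-identical families are uncertain.

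The statistics were tested on simulated data. For the gene-body 5hmC test on 16815 genes, 100% of 50 genes raised 1.5-fold and 96% of 50 genes lowered 1.5-fold were recovered, against 90% and 80% at 1.2-fold; 0.0903% of unchanged genes were called, and these made up 7.58% of the calls, above the nominal 5%. With no difference simulated, the window test called 0% of windows, and with an even overdispersion of 1.4 it called 0.109% in 5mC and 0.147% in 5hmC. The gene list test gave p under 0.05 for 4% of 200 random lists of 20 genes. These were drawn from the whole genome, so lists of neighbouring genes were not covered. The strand test recovered 89.3% of 2000 differing CpGs and called 0.0273% of equal ones. The simulated difference was larger than the median of the CpGs called in the data, 16.2 points in 5hmC and 28.9 in 5mC. Recovery of smaller differences was not simulated.

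Alternatives covered coverage minima of 5 and 10 calls, very deep sites, the estimator, subtraction of the mitochondrial level, window sizes, the width of gene ends, gene filters, the variance, 5hmC as a share of modified calls, unmatched random lists and each replicate left out.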

Results

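The data collected were counts of 5mC, 5hmC and unmodified calls at CpG cytosines of E14 mouse embryonic stem cells, a male blastocyst-derived line. One group of 4 technical replicates was measured, with 521879873 to 709778597 calls each, so no comparison between conditions was possible. The comparisons concern regions and genes within these cells, and the replicates against each other.

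The first question was how much of each modification the genome carried. On the autosomes 63.4% ± 0.0619 of calls were 5mC and 3.92% ± 0.0206 were 5hmC (SD, n = 4), so that 5hmC made up 5.83% ± 0.0304 of modified calls. The X chromosome, single-copy in this line, held less 5hmC than the autosomes, 3.06% ± 0.0255, while its 5mC, 64.5% ± 0.0841, lay within the range of the autosomes, 58.1% on chromosome 11 to 66.2% on chromosome 3 (SD, n = 4). Its 5hmC lay below that of every single autosome, which ranged from 3.62% on chromosome 3 to 4.31% on chromosome 11. The Y chromosome held 71.0% ± 0.301 5mC and 2.00% ± 0.0654 5hmC. Mitochondrial DNA, which served as the background of false calls at unmodified cytosines, gave 0.0772% ± 0.0120 5mC and 0.0519% ± 0.00658 5hmC. The autosomal 5hmC level was 75.6-fold higher, a comparison that does not cover 5mC called as 5hmC. Each of these differences had the same sign in 4 of 4 replicates, and the exact two-sided sign-flip test cannot go below 1 in 8 with 4 replicates, so 0.05 was out of reach.

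The next question was how far the technical replicates differed. Across 10-kb autosomal windows, Pearson's r between pairs of replicates was 0.989 to 0.991 for 5mC and 0.929 to 0.939 for 5hmC; windows are not independent replicates. In 5mC, 4351 of 240819 windows differed between replicates, or 1.81%, and in 5hmC 20 of 221693, or 0.00902%. The mean chi-square per degree of freedom was 1.46 for 5mC and 1.17 for 5hmC, where independent calls give about 1. Correlation of calls on the same molecule raises this factor without any difference between replicates. The window test takes calls as independent, so a window counted as differing need not be a difference between replicates. Leaving out any 1 of replicates 1, 2, 3 and 4 lowered the 5mC share to between 0.995% and 1.09% and the 5hmC count to between 0 and 6 windows. The 5mC share was 0.434% in 1-kb and 11.7% in 100-kb windows. In the number of calls per window, every pair of replicates had a dispersion of 2.00 or more. A read can give several calls, so this value need not be a difference between replicates either.

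Gene ends and gene bodies carried different mixtures of the modifications. At the CpG-denser ends of coding genes, which often hold the CpG island of a promoter, 5mC was 9.79% ± 0.0452 and 5hmC 1.29% ± 0.00663 (SD, n = 4). The opposite ends held 61.8% ± 0.0718 5mC and 4.92% ± 0.0258 5hmC, and coding gene bodies 64.7% ± 0.0673 and 4.31% ± 0.0225. Other annotated genes held 66.4% ± 0.0538 5mC and 4.09% ± 0.0214 5hmC. Sequence outside genes had the most 5mC of these classes, 69.3% ± 0.0614, with 3.65% ± 0.0223 5hmC. Coding gene bodies exceeded the sequence outside genes by 0.665 points of 5hmC, in 19 of 19 autosomes, with a permutation p of 1e-05, the smallest 100000 sign flips can give. The difference of coding bodies from other annotated genes in 5mC was -1.68 points, and -0.305 points with CpG-denser ends of 1000 bp, where its permutation p was 0.698. The levels above are over all calls. As a share of modified calls, 5hmC was highest at the CpG-denser ends, 11.6%, and 7.38% at the opposite ends. It was 6.25% in coding bodies, 5.81% in other annotated genes and 5.00% outside genes.

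With distance from the CpG-denser end, 5mC rose in every step while 5hmC rose and then fell. Within 0.5 kb 5hmC was 1.29% ± 0.00663, at 5 to 10 kb it reached 4.91% ± 0.0206, and beyond 50 kb it was 3.54% ± 0.0235 (SD, n = 4). Over the same classes 5mC went from 9.79% ± 0.0452 to 62.0% ± 0.0610 and 72.5% ± 0.0724. As a share of modified calls, 5hmC fell in every step. That share was 11.6% within 0.5 kb, 7.33% at 5 to 10 kb and 4.66% beyond 50 kb. The peak at 5 to 10 kb thus holds for 5hmC over all calls.

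**Figure D1:**
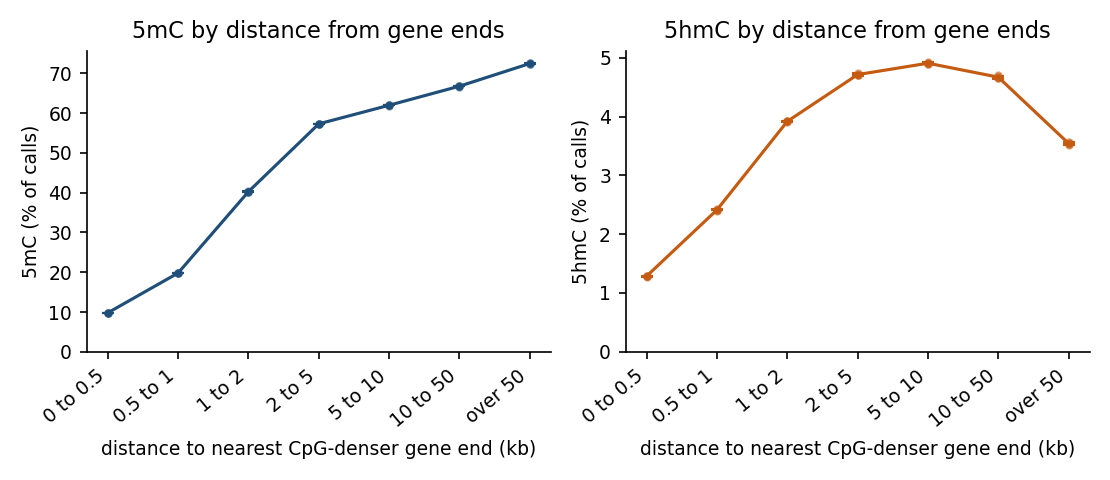
Percent of calls that were 5mC (left) and 5hmC (right) against distance in kb to the nearest CpG-denser gene end, on autosomes. Points are the 4 replicates, bars the SD and lines the means; 5hmC is highest at 5 to 10 kb (4.91%) and 5mC beyond 50 kb (72.5%).

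CpG density separated gene ends. The 10023 ends with 40 or more CpGs had 1.51% ± 0.0116 5mC and 0.480% ± 0.00816 5hmC, and 96.8% of them lay under 10% 5mC. The 2676 ends with under 10 CpGs had 70.4% ± 0.105 5mC and 3.41% ± 0.0339 5hmC. The 6686 ends of intermediate density, 10 to 39 CpGs, had 31.9% ± 0.0792 5mC and the most 5hmC of the 3 classes, 4.04% ± 0.00589 (SD, n = 4). They exceeded the CpG-poor ends in 5hmC by 0.637 points, in 17 of 19 autosomes (permutation p = 1e-04).

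The level of 5hmC also followed total modification. In 1-kb windows it was 0.647% where total modification was under 10%, peaked at 7.28% in windows of 40 to 50%, and fell to 3.30% at 80 to 90% and 2.45% above 90%. The readings from replicates 3 and 4 and from replicates 1 and 2 were 7.27% and 7.29% in the 40 to 50% class. In 10-kb windows that class held 4.76%.

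**Figure D2:**
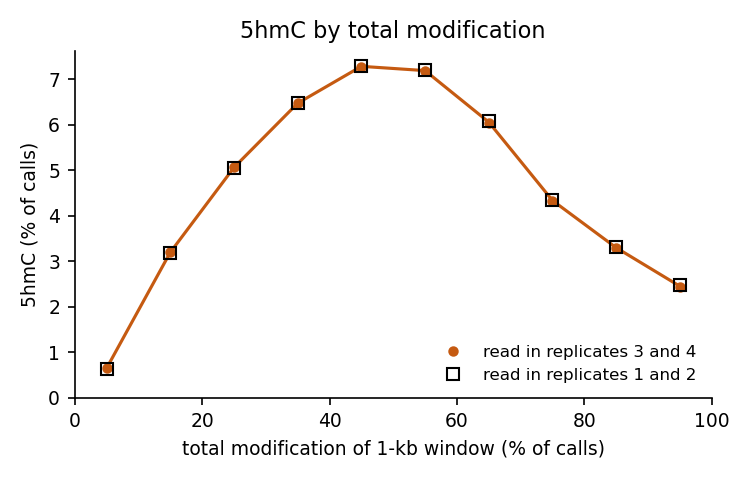
Percent of calls that were 5hmC against total modification (5mC plus 5hmC, percent of calls) of autosomal 1-kb windows in 10-percent classes. Circles and squares are the readings in each pair of replicates, windows having been binned in the other pair, and the line is their mean; the highest class is 40 to 50% (7.28%).

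Individual gene bodies spanned a wide range of 5hmC around the overall level of 4.36%. Of 16815 coding genes, 7273 were called higher, 7076 lower and 2466 neither; 1955 were at least 1.5-fold higher and 3226 at least 1.5-fold lower. The central 80% of genes lay between 2.28% and 6.69%. The highest body belonged to Il13, a type 2 cytokine gene (chromosome 11, 53631323 to 53634702), at 13.8% ± 1.64 over 3861 calls. It was followed by Pla2g2e, a secreted phospholipase (11.7% ± 0.653), Tlr12, a Toll-like receptor (11.6% ± 1.43), Ptgds, a prostaglandin D synthase (11.6% ± 1.43), and Irf7, an interferon regulatory factor (11.4% ± 0.831). Cd79a, a B-cell receptor subunit, was at 11.3% ± 0.449, the forkhead gene Foxi2 at 11.3% ± 2.81 and the water channel gene Aqp3 at 11.2% ± 0.669 (SD, n = 4). Most of these bodies were small: Il13 held 20 CpGs, the minimum for a test, Ptgds 23, Cd79a and Foxi2 27 each and Irf7 29. Tlr12 held 30, Pla2g2e 41.5 and Aqp3 65, so that Aqp3 alone reached the alternative minimum of 50. Whether small size favoured these extremes was not tested. The levels from Pla2g2e to Aqp3, 11.7% to 11.2%, differed by no more than their SDs, so their order cannot be read.

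Of the 8 lowest bodies, 6 were nearly free of both modifications. H2az1, which encodes the histone variant H2A.Z, gave 0 5hmC calls of 4575, which allows up to 0.0656%. Epop, encoding a Polycomb-associated protein, was at 0.0259% ± 0.0296, the forkhead gene Foxd1 at 0.0397% ± 0.0264, and Mcl1, an anti-apoptotic gene, at 0.0624% ± 0.0346 (SD, n = 4). The ribosomal protein gene Rps2 was at 0.0728% ± 0.0508 and Mid1ip1 at 0.0834% ± 0.114. These levels lay below the mitochondrial background of 0.0519% or within their SD of it. Neither the levels nor their order can therefore be separated from false calls. The bodies of Mcl1 and Rps2 held 184 and 92 CpGs and their denser ends 7 and 6. Their values thus describe CpG-dense sequence that lay within the body as defined here. Ip6k2 gave 0 of 228 calls and Mrgpra2a 0 of 299, allowing 1.32% and 1.00%, with 2.63% ± 1.75 and 22.7% ± 1.93 5mC; the first lies mostly in sequence without calls and the second in a family of near-identical genes, and both are uncertain. The bodies of the high group held 46.4% to 57.6% 5mC, and those of H2az1, Epop, Foxd1, Mcl1, Rps2 and Mid1ip1 at most 0.209%. With 5hmC taken as a share of modified calls, 8157 genes were called higher and 6730 lower, of which 6533 and 5731 were shared with the calls above, while 949 genes called lower above were called higher and 125 called higher above were called lower.

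The highest gene-end 5hmC was found at Abca16, an ABC transporter gene, with 15.3% ± 1.79 over 13 CpGs, and at Fgf21, a metabolic hormone gene, with 15.0% ± 2.60. Chrnd, an acetylcholine receptor subunit, had 14.9% ± 1.81, Mageb4 14.8% ± 4.74 over 405 calls, Dcstamp, a gene of cell fusion in osteoclasts, 14.7% ± 1.61, and S100a16 14.7% ± 1.94 (SD, n = 4). Their 5mC ranged from 30.9% to 57.5%.

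The gene lists fixed beforehand were then compared with matched random lists. Germline genes, which are active in germ cells and meiosis, stood furthest apart in 5hmC at their CpG-denser ends. The median of 25 measured members was 35.7% 5mC and 7.95% 5hmC, against 2.57% and 0.787% in random lists (adjusted permutation p = 0.0012 for each). Dpep3 had 82.0% ± 1.75 and Fkbp6 78.9% ± 3.48 5mC, and the lowest were Tex14 at 3.39% ± 0.667 and Rpl10l at 15.3% ± 2.49 (SD, n = 4). In their bodies 5hmC was lower, with a median of 3.01% against 4.39% (adjusted permutation p = 0.0105); 16 of 23 members were lower and 5 higher, the same counts as adjusted over the list alone. As a share of modified calls, the germline ends lay 6.11 points below random lists (a difference of -6.11, adjusted permutation p = 0.0725). Against unmatched lists their 5mC difference was 32.1 points, with an adjusted permutation p of 0.110.

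Naive pluripotency genes, the transcription factors and markers of ground-state stem cells, had low levels at their ends. The median of 28 members was 0.844% 5mC against 6.05% (adjusted permutation p = 0.0037) and 0.184% 5hmC against 1.63% (adjusted permutation p = 0.0012). Their bodies were split, with 12 of 25 higher and 12 lower, also when adjusted over the list alone, and a median of 3.94% against 4.28% (adjusted permutation p = 0.548). The core factor Sox2 was at 0.117% ± 0.0903 and Klf2 at 0.131% ± 0.111, while Tcl1 had 8.40% ± 0.721 and Dppa4 7.63% ± 0.703 (SD, n = 4). As a share of modified calls the body difference was 8.26 points, above random lists (adjusted permutation p = 0.000764), and the end difference 0.959 points and not called. The 5hmC at these ends, 0.184%, lay above the mitochondrial 0.0519%. False calls may still make up part of it, and no share with that background removed was calculated. Against unmatched lists the 5mC difference had an adjusted permutation p of 0.154. Of levels over all calls, the list of primed or formative pluripotency genes was called in none of the 3 measures, with 4 of 12 bodies higher and 6 lower, the same adjusted over the list alone; Wnt8a had 8.49% ± 0.570, Lef1 6.51% ± 0.0902 and Pou3f1 0.458% ± 0.0823 5hmC. This list lay above random lists as a share of modified calls, by 8.30 points in bodies (adjusted permutation p = 0.000764) and 19.8 at ends (adjusted permutation p = 0.0084). The levels at these ends were low, 0.211% 5hmC and 0.134% 5mC, against 0.0519% and 0.0772% in mitochondrial DNA. In that background 5hmC made up 40.3% of modified calls, so false calls may add to the higher share at ends. How much they add was not tested, as no share with the background removed was calculated.

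Mesoderm regulators were higher in all 3 measures. Their body median was 5.78% against 4.23% (adjusted permutation p = 0.0233), with 12 of 16 members higher and 3 lower, also when adjusted over the list alone. Foxf1 had 10.6% ± 1.06, Mixl1 8.63% ± 0.651, Tal1 4.07% ± 0.128 and Hand2 2.49% ± 0.0639 (SD, n = 4). Their ends had 3.73% 5hmC against 0.610% (adjusted permutation p = 0.0012) and 8.70% 5mC against 1.92% (adjusted permutation p = 0.0076). The 5hmC difference at these ends was -1.39 points as a share of modified calls, and the 5mC difference had an adjusted permutation p of 0.506 against unmatched lists.

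Neural regulators and the Hox clusters, which pattern the body axis, had low 5hmC in their bodies. The neural median was 3.11% against 4.38% (adjusted permutation p = 0.0215), with 12 of 19 members lower and 4 higher, and the Hox median 3.12% against 4.26% (adjusted permutation p = 0.0168), with 19 of 31 lower and 7 higher; both pairs of counts were the same adjusted over the list alone. Neurog2, a proneural factor, had 0.164% ± 0.0369, Olig2 0.520% ± 0.134, Pax7 5.75% ± 0.104 and En1 5.89% ± 0.594 (SD, n = 4). Among Hox genes, Hoxa7 had 0.561% ± 0.0625, Hoxb2 0.566% ± 0.233, Hoxc10 5.88% ± 0.862 and Hoxd4 6.84% ± 0.334. The Hox ends were higher in 5hmC, 1.58% against 0.598% (adjusted permutation p = 0.0076), with an adjusted permutation p of 0.415 against unmatched lists. As a share of modified calls both body differences turned positive, 17.8 and 18.0 points (adjusted permutation p = 0.000764 for each), and without replicate 4 the Hox body call was lost (adjusted permutation p = 0.0579).

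Imprinted genes, expressed from 1 parental copy, had a median 5mC of 20.03% at their ends against 1.97% (adjusted permutation p = 0.0021; 0.401 against unmatched lists). The 14 measured ends ran from Grb10 at 0.550% ± 0.187, Zrsr1 at 5.80% ± 1.43, Peg10 at 6.14% ± 1.73 and Sgce at 6.47% ± 1.151 to Mest at 40.5% ± 2.42, Peg13 at 52.8% ± 2.97, H19 at 56.5% ± 4.28 and Snrpn at 58.8% ± 4.11 (SD, n = 4). Between them lay Mcts2 at 10.1% ± 0.416, Kcnq1ot1 at 10.3% ± 1.08, Peg3 at 19.7% ± 2.66, Nnat at 20.3% ± 2.03, Plagl1 at 21.3% ± 1.14 and Airn at 23.0% ± 5.62. Of their 9 tested bodies 3 were higher and 5 lower in 5hmC, also when adjusted over the list alone. The denser end need not be the imprinted control region, and for Snrpn it held only 6 CpGs. The ends of Peg10 and Sgce, at 4747306 and 4747204 on chromosome 6, share most of their windows and are not independent.

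Housekeeping genes had low ends, 0.143% 5mC against 0.799% (adjusted permutation p = 0.0232) and 0.113% 5hmC against 0.323% (adjusted permutation p = 0.0174), the second with an adjusted permutation p of 0.0676 without replicate 1. As a share of modified calls that 5hmC difference was 7.44 points and not called, at levels too close to the mitochondrial background for its direction to be read. Of 18 bodies, 5 were higher, among them Polr2a at 6.37% ± 0.115 and B2m at 5.48% ± 0.866, and 9 lower, among them Gapdh at 0.313% ± 0.152 and Eef1a1 at 0.478% ± 0.282. Genes of terminally differentiated tissues had 71.8% 5mC at their ends against 35.9% (adjusted permutation p = 0.0168). Of 17 bodies 9 were higher and 7 lower in 5hmC; the muscle genes Ckm and Acta1 had 7.84% ± 0.424 and 7.02% ± 0.750, and Alb, the albumin gene, and Ptprc, the leukocyte antigen CD45, had 1.95% ± 0.0886 and 2.58% ± 0.0924 (SD, n = 4). Of 1106 listed olfactory receptors, 747 ends were measured, with 77.8% 5mC against 74.1% (adjusted permutation p = 0.0012). The random lists for these ends could hold receptors too, so their differences and p-values are uncertain. The 22 measured receptor bodies had less 5hmC, 2.14% against 4.06% (adjusted permutation p = 0.0012). Of these bodies 18 were lower, such as Olfr536 at 1.25% ± 0.221 and Olfr183 at 1.35% ± 0.192, and 2 higher, Olfr70 at 4.98% ± 0.452 and Olfr1349 at 6.08% ± 0.525; receptors of this family can share reads. Their end 5hmC was 1.82% against 2.72% in matched lists, and 0.822 points above unmatched ones. In these 3 lists the counts were the same adjusted over the list alone.

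Genes of the DNA methylation machinery, endoderm, trophectoderm and fibroblasts, the last a possible other cell type, were called in none of the 3 measures over all calls. In the machinery list 11 of 16 bodies were higher and 3 lower; Tet1, which oxidises 5mC, had 7.53% ± 0.0307, Uhrf1, a maintenance factor, 7.05% ± 0.104, Mbd3 2.83% ± 0.308 and Zfp57 2.81% ± 0.221 (SD, n = 4). As a share of modified calls its body difference had an adjusted permutation p of 0.0202, 3.35 points above random lists. In the endoderm list 4 of 11 were higher and 7 lower, with Gata4 at 5.14% ± 0.161, Sox7 at 5.09% ± 0.405, Foxa2 at 1.38% ± 0.185 and Sox17 at 1.25% ± 0.177. In the trophectoderm list 5 of 11 were higher and 6 lower, with Krt8 at 7.16% ± 0.158, Tead4 at 6.74% ± 0.103, Esx1 at 1.34% ± 0.109 and Ascl2 at 0.309% ± 0.119; as a share of modified calls its body difference was 6.84 points (adjusted permutation p = 0.0014). In the fibroblast list 4 of 10 were higher and 5 lower, with Thy1 at 7.84% ± 0.361, Fn1 at 6.59% ± 0.145, Lum at 2.24% ± 0.239 and Dcn at 1.97% ± 0.109 (SD, n = 4). These counts, too, were the same adjusted over the list alone.

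**Figure D3:**
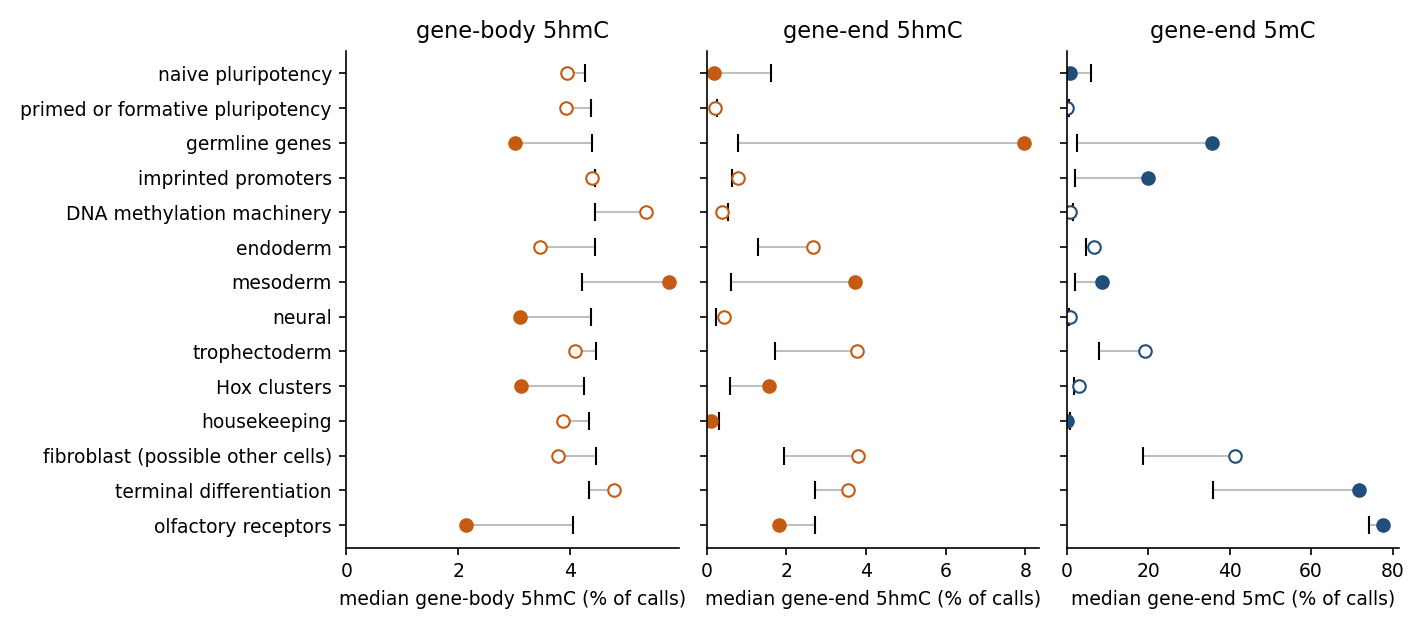
Median level (percent of calls) of each gene list in gene-body 5hmC, gene-end 5hmC and gene-end 5mC. Circles are the list medians, filled where the adjusted permutation p was under 0.05, and vertical ticks the medians of matched random lists; germline ends stand at 7.95% 5hmC and 35.7% 5mC.

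The bases beside a CpG went with its 5hmC. Of the 16 contexts, ACGG had the most, 5.30% ± 0.0175, and TCGC the least, 2.55% ± 0.0228 (SD, n = 4), while their 5mC was 66.3% ± 0.0528 and 64.2% ± 0.0766. Within single CpGs, the strand reading ACGA exceeded the strand reading TCGT by 1.95 points of 5hmC ± 0.00352, and CCGA exceeded TCGG by 1.56 ± 0.0139. Across the genome the plus and minus strands differed by 0.00445 points in 5hmC and 0.0139 in 5mC (permutation p = 0.0207 and 0.0486), and both calls were lost without replicate 4 (permutation p = 0.0844 and 0.144). Of 3360850 CpGs tested, 26761 differed between strands in 5hmC, or 0.796%, with the same sign in all 4 replicates for 92.2% of them. These CpGs were picked on counts pooled over the same replicates, which favours such agreement, so it is no separate support. In 5mC 17470 of 10479360 differed, or 0.167%.

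Read depth was missing over part of Hprt, a purine salvage gene and one of the housekeeping list (chromosome X, 52988078 to 53021660). A run of 152 listed CpGs from 52963705 to 52999211 had 0 reads in each of the 4 replicates, and Hprt was therefore measured over part of its length.

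**Figure D4:**
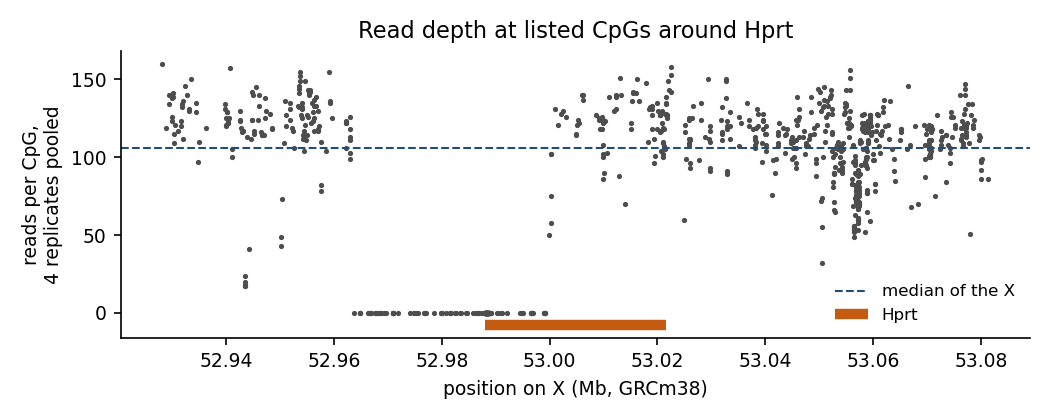
Reads per listed CpG, summed over 4 replicates, against position on the X chromosome in Mb. Points are CpGs, the dashed line is the median of the X (106 reads) and the bar is Hprt; 152 neighbouring CpGs have 0 reads.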

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

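The test of opposite cytosines was chosen after the result had been seen, and so was the definition of lost CpGs.

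In 110 groups of 4 replicate values, 2 held a value far from the other 3, fewer than the 1 in 20 that chance gives, so neither stands out from chance. At the gene end of Chrnd, a muscle acetylcholine receptor subunit, 1 replicate had 17.6% 5hmC and the others 13.8% to 14.1%. In the body of Mbd3, a methyl-CpG-binding domain protein, 1 replicate had 2.36% 5hmC and the others 2.95% to 3.00%.

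A signal also appeared in reads that entered no level: 5.69% of autosomal reads fell outside the 3 call classes. At 337182 autosomal cytosines, 1.38% of those with at least 20 reads, 90% or more of the reads did so. A candidate explanation is a base of this cell line that differs from the reference, so that the CpG is lost and the opposite cytosine is no longer a target of methylation. The opposite cytosines had a median total modification of 0%, and pooled 0.0283%, against a median of 78.8% elsewhere, which is what a lost CpG predicts. Sequencing errors or failed classification remain open for other reads outside the classes, since without the 693170 cytosines of CpGs with 50% or more of the reads of either strand outside them the share was still 4.38%.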

How the results depend on the processing

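No paired analysis was possible because the series holds a single group. The alternatives that leave out CpGs lost in the cell line or adjust over 1 list alone were chosen after seeing the data. Unless a cause is given, the cause was not tested. Of 500 values of results under alternatives, 435 were counted as unchanged. Tested differences had to keep their direction and side of the threshold, and levels to move by less than the replicate SD. For classes of total modification, the difference between the 2 readings replaced the SD. Numbers of genes and shares of windows had to stay within 1.5-fold, which single genes can pass while changing side. Leaving out each technical replicate gave 74 of the 500 values.

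Autosomal 5mC was 63.4% with at least 10 calls (63.44), 62.3% as the mean of per-cytosine fractions and 64.3% without lost CpGs. With the mitochondrial level subtracted it was 63.3% and 5hmC 3.87%; without lost CpGs 5hmC was 3.98%. Windows differing in 5mC were 0.434% at 1 kb and 11.7% at 100 kb, and in 5hmC 0.0195% and 0%. With 1 replicate left out they ranged from 0.995% to 1.09% in 5mC and from 0% to 0.00271% in 5hmC. A test without 1 replicate holds fewer calls, and whether this lowered the shares was not tested. In windows of 40 to 50% total modification, 5hmC was 4.76% at 10 kb and 7.41% to 7.51% with 1 replicate left out; at 80 to 90% the latter range was 3.32% to 3.36%. Coding bodies minus other genes in 5mC was -0.305 points with CpG-denser ends of 1000 bp. With 1 replicate left out, the strand difference ranged from 0.00354 to 0.00562 points in 5hmC and 0.0120 to 0.0166 in 5mC.

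The choice of denominator mattered most for gene lists. As a share of modified calls, 6 of 11 called 5hmC results changed sign. Among these, housekeeping ends lay too close to the mitochondrial background for the sign to be read, and false calls may make up part of the 5hmC at naive ends. The share of 5hmC in modified calls fell from 25.7% to 2.75% as the total modification of 1-kb windows rose. Differences from random lists in gene bodies were then 8.26 points for naive and 8.30 for primed pluripotency, 17.8 for neural, 18.0 for Hox, 6.84 for trophectoderm, 3.35 for the methylation machinery, 1.45 for endoderm, 1.71 for housekeeping, 0.132 for imprinted and -0.0109 for terminal differentiation genes, of which the first 6 were past the threshold. At gene ends they were 0.959 for naive and 19.8 for primed pluripotency, -6.11 for germline, -20.4 for imprinted, 3.05 for the machinery, -1.39 for mesoderm, 4.73 for Hox, 7.44 for housekeeping and -7.42 for terminal differentiation genes, with the primed, imprinted and terminal differentiation lists past the threshold. The mitochondrial background, 0.0519% 5hmC, had a share of 40.3%. Housekeeping ends, at 0.113% 5hmC, lay too close to it for their share to be read. Naive and primed ends, at 0.184% and 0.211%, lay above it, but how far false calls changed their shares was not tested.

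Against unmatched random lists the gene-end 5mC differences were -2.84 for naive and -3.45 for primed pluripotency, 32.1 for germline, 16.1 for imprinted, 5.08 for mesoderm, -2.68 for neural and -0.700 for Hox genes. In gene-end 5hmC they were -0.239 for imprinted, -0.544 for neural, 0.579 for Hox, 2.54 for terminal differentiation and 0.822 for olfactory receptor genes, and in gene-body 5hmC 0.00291 for imprinted genes; past the threshold were primed genes in 5mC and terminal differentiation and olfactory receptor genes in 5hmC. With 1 replicate left out, gene-body differences ranged from -0.582 to 0.0213 for naive, -0.0999 to 0.00753 for imprinted and -1.32 to -0.947 for Hox genes, and the gene-end 5hmC difference of housekeeping genes from -0.224 to -0.185. Depth limits small genes and gene ends: Mageb4 rested on 405 calls and Ip6k2 on 228.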

Other observations

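The patch-contig intervals of the second definition below were chosen after the result of the first had been seen, and the summing of calls over windows in the test of misreading was chosen after its first result had been seen; the other tests in this part were written before their results.

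Of 26089 autosomal 1-kb windows with at least 30 CpGs, 1487 had a total modification of 35 to 65% in every replicate. The windows with the most CpGs, named after their values were seen, lay in Zfp993, a zinc finger gene, and in Dazl, a germ-cell RNA-binding protein gene. The Zfp993 window (chromosome 4, 146942000 to 146942999) had 34.1% ± 4.12 5mC and 7.32% 5hmC. The Dazl window (chromosome 17, 50293000 to 50293999) had 47.1% ± 2.61 5mC and 8.04% 5hmC. Runs of CpGs without a call lay on both sides of the Zfp993 window, from 146808860 to 146841085 and from 146978287 to 147015793. Whether uncertain mapping affected its level was not tested. Imprinting, with 1 methylated copy, is a possible explanation of some of the 1487 windows and stays open. Within 10 kb of a gene of the imprinted list lay 3 of them, or 0.202%, against 0.138% of all 26089 CpG-dense windows. Only 36 CpG-dense windows lay there, so the share could not have passed 2.42%. Sequence near the listed genes therefore cannot account for most of the 1487 windows. Imprinted genes outside the list were not tested.

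Hprt, the purine salvage gene on X (52988078 to 53021660), had no reads over part of its length. A run of 152 listed CpGs from 52963705 to 52999211, 35.5 kb, held 0 reads in each of the 4 replicates, while the flanks had 111% and 116% of the median depth of the X. A deletion in this cell line is a candidate explanation, and the sharp edges are consistent with it; the sequence of the junction was not examined.

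The peak of 5hmC at intermediate modification could reflect 5mC read wrongly as 5hmC at a fixed rate. That predicts less 5hmC at 40 to 60% than above 80% total modification; the 40 to 60% windows held 2.20 times as much with calls summed over windows (2.52 times from the unweighted means of the classes, calculated first), which argues against a fixed rate of misreading as the main source.

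The strands of a CpG differed in 5hmC mainly by sequence. Among differing CpGs in non-palindromic contexts, 95.6% had the higher strand on the side usual for the context, which a context-dependent bias of the calls predicts. Misreading of 5mC at a context-dependent rate predicts a larger difference where there is more 5mC, and the tables argue against it: the difference in windows of 80 to 90% was 0.535 times that in windows of 40 to 50%, with 0.292 to 0.631 over the 6 context pairs. A detection rate or an enzyme preference that scales with the 5hmC present may account for it, since the ratio of paired contexts changed by a median factor of 1.04 (0.942 to 1.149). A technical detection rate and a preference of the TET enzymes predict the same values here, and no biological explanation was tested.

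Of the autosomal cytosines, 836084, or 3.34%, had no call in any replicate. Reads mapping also to alternative and patch contigs could be lost, and 2 definitions of the affected positions were tried. Positions shared exactly with 17 contigs had no call at 99.9%, but held 7.95% of all cytosines without a call, short of the 20% set beforehand. Whole intervals of 49 placed contigs, a definition chosen after that result, had no call at 98.9% against 2.58% outside, and held 23.4%. Such contigs may therefore explain part of the loss, how much depends on the definition, and 76.6% lay outside both.

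The list holds fewer CpGs than a mouse genome would. Leaving out CpGs in repeat-masked, lower-case sequence is a candidate explanation: the next listed CpG was at a median of 294 bp on the side of a lower-case base and 56 bp otherwise, a ratio of 5.25. The levels above may therefore describe mostly sequence outside repeats.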
